A study of Mus musculus with 12 samples.

How the data were processed

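Gene expression was measured on 12 two-colour Agilent mouse arrays, 1 per sample. AML12 and Hepa 1-6 cells were grown in serum-containing medium, which only for AML12 also held dexamethasone and insulin, and serum and additives were withdrawn overnight, per the labels' protocols. The cells then stayed without serum as controls, or received 200 ng/mL of ovine pituitary prolactin or 10 µg/mL of actinomycin D for 8 h. Total RNA was extracted with Trizol, labelled with Cy5, and hybridised with Cy3-labelled Universal Mouse Reference RNA, a pool from 11 mouse cell lines, per the labels' protocols. The dye orientation was the same on every array and no dye was swapped. Each of the 6 groups held 2 arrays, which the series design describes as biological replicates.

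The deposited values were the authors' normalized log10 ratios of sample over reference for 45018 features per array, produced with Agilent Feature Extraction per the submitters' processing notes, whose version and settings are not given in the sources used here. The base of the logarithm is not stated either; base 10 is the convention of that software and was assumed. The median was 0 on every array with exact zeros counted, and values ran from -3.12 to 2.94. Exact zeros made up 12.7% of all values, 4737 to 7621 per array, whereas 96 to 117 other values per array lay within 0.001 of 0. Exact zeros were therefore treated as features with no ratio. There were 2289 features at zero on all 12 arrays and 7065 on some. No background or saturation marks were used, so very low ratios can lie at the detection floor. The number of arrays limits the precision.

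Ratios were converted to log2 (3.32 per log10 unit) with no further scaling. Of the features, 33653 carried 1 gene symbol in the platform annotation, 56 carried several and 11309 none, and 99.6% of those with 1 symbol were matched by Entrez identifier to the reference gene table. The 35664 features with a ratio on all 12 arrays were kept, and the 28519 of them with 1 symbol were averaged per gene, which gave 16549 genes, 9482 of them with 1 feature and 7067 with several. Features with several symbols or none were counted only where every feature was tested by itself.

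Genes were tested in 1 linear model over the 12 arrays with a mean per group, using limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided). The 6 groups shared 1 estimate of the spread with 6 residual degrees of freedom, and the prior added 1.84. Each treatment was compared with the control of the same line, the mean of both lines was tested for each treatment, the difference between the lines' responses was tested as an interaction, and the 2 control groups were compared. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A gene is said to have risen, fallen or changed only where it passed. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

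Before the data were examined, 22 gene lists were fixed, together with the model, the alternatives and the rule for naming genes. Each list was tested with camera at its preset correlation of 0.01, with the Benjamini-Hochberg adjustment over the 22 lists of a comparison, and also with camera at an estimated correlation and with fry. List members past the threshold were counted with p-values adjusted over all genes and, separately, adjusted over the list alone. Within a line, the genes named were the 10 with the largest rise and the 10 with the largest fall among genes past the threshold for which both treated arrays lay beyond both control arrays. Predicted and unnamed gene models were left out, and 5 per direction were named in the comparisons across lines. Where fewer than 5 passed in a direction, genes with the largest moderated t were added and named as not past. Up to 4 members of each list were named per comparison, the 2 with the largest rise and the 2 with the largest fall that passed, or the 1 with the largest moderated t where none did. Of the single genes fixed for every comparison, Myc is reported and the other was not analysed here. Not every gene that the rule allows is printed.

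Alternatives were median centring of each array, quantile normalization, features with a ratio in at least 1 sample of every group, leaving out the lowest 20% of mean ratios, using the feature with the highest mean ratio per gene, testing every feature by itself, a robust prior, a replicate block, fits restricted to 1 line or to the compared groups, a minimum fold of 2, and leaving out each array in turn. Keeping exact zeros as a ratio of 1 was added after seeing the data, as were 4 further gene lists. Camera p-values of the hypoxia-inducible and acute-phase lists are given without members seen before. The list of other glucocorticoid-responsive genes kept some, Ddit4 among them, and p-values were adjusted over these 3 lists. Correlations between the responses to both treatments within a line were set beside 100 simulated sets of unchanged groups that share the controls. The steps were tested on simulated data with the real genes' control means. Variances were drawn at random from limma's fitted prior and capped, with normal noise alike in all groups. The simulation thus met the model's own assumptions, and recovery on the real arrays may be lower. For prolactin in AML12, 50 of 16549 genes were changed per size. Limma recovered 46% of genes changed by 0.5 on the log2 scale, 74% at 1, 98% at 2 and 98% at 3. For the same genes the difference between lines was recovered for 10%, 54%, 92% and 96%. Of the 167 genes called there, 9 were unchanged, and 0 were called in a comparison simulated with no change.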

Results

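The arrays compared 2 mouse liver cell lines, AML12 and Hepa 1-6, under 2 treatments, with 2 biological replicates in each of 6 groups. AML12 is a hepatocyte line from mice that carry a TGF-alpha transgene, and Hepa 1-6 is a hepatoma line. The labels name hepatoma as the source of both. Prolactin is a pituitary hormone that acts through JAK2 and STAT5, and actinomycin D blocks transcription by binding DNA. Between 37397 and 40281 of the 45018 features held a ratio on each array. Replicate arrays correlated at 0.975 to 0.985 across genes. Control and prolactin groups correlated at 0.985 in AML12 and 0.990 in Hepa 1-6, and the 2 control groups at 0.616. Changes are log2 differences between groups of 2 arrays, on the authors' normalization of each array, with the standard error and adjusted p from limma. They rest on the assumption that the deposited ratios are log10. If the base were 2, all log2 values given here would be smaller by a factor of 3.32, with the same signs and p-values. Every gene given as one of the largest changes within a line lay beyond both controls on both treated arrays. The naming rule required this, so it is no separate evidence for those changes.

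The first comparison asked which genes prolactin changed in AML12. Cish, a STAT5 target that inhibits cytokine signalling, rose by 2.17 ± 0.13 (adjusted p = 0.00066), and Socs2, which encodes another such inhibitor, rose by 0.71 ± 0.06 (adjusted p = 0.0030). Pde4b, whose product degrades cyclic AMP, rose by 1.56 ± 0.09 (adjusted p = 0.00053), Edn1, which encodes endothelin 1, by 1.56 ± 0.13 (adjusted p = 0.0030), and the ubiquitin ligase gene Fbxo32 by 1.10 ± 0.08 (adjusted p = 0.0022). The largest falls included genes known to be induced by glucocorticoids, which were Per1 at -1.82 ± 0.10 (adjusted p = 0.00042), Tsc22d3 at -1.53 ± 0.05 (adjusted p = 5.6e-05), Klf15 at -1.48 ± 0.09 (adjusted p = 0.00084) and Klf9 at -1.20 ± 0.06 (adjusted p = 0.00033). No such shift was found in 25 other glucocorticoid-responsive genes, listed afterwards (median -0.0747, camera adjusted p = 0.713), and the glucocorticoid-induced gene Tat rose by 0.90. Bcl6, which encodes a transcriptional repressor, changed by -0.82 ± 0.06 (adjusted p = 0.0019), and Pim3, a kinase gene, by -0.85 ± 0.10 (adjusted p = 0.017). Of 16549 genes, 210 passed the threshold, 119 higher and 91 lower, and 29 of them changed at least 2-fold. The other genes among the 10 largest rises were Cxcl10, Npy5r, Lmo7, Chst15, Gbp3 and Ch25h, between 1.05 and 1.31. Npy5r and Gbp3 had mean log2 ratios of -6.38 and -7.49 in AML12 controls, where ratios can lie at the detection floor. The size of these rises is therefore uncertain. The other large falls were Gcnt3, Akr1c20, Wnt5a, Armc3, Klhl41 and Nlrp4c, between -1.86 and -1.18. Armc3 and Nlrp4c had mean log2 ratios of -5.10 and -5.13 with prolactin, so the size of these falls is uncertain for the same reason. Cish, Pde4b, Edn1, Fbxo32, Chst15, Per1, Tsc22d3, Klf15 and Klf9 stayed past the threshold whichever array was left out, and the other 11 of these 20 genes did not. The count of 210 fell to 69 and 30 without the first and second AML12 control, and to 77 without the first prolactin array. It fell to 80 without either Hepa 1-6 control, to 57 without either Hepa 1-6 prolactin array and to 115 without either Hepa 1-6 actinomycin D array. Fits with limma on the 6 AML12 arrays or the compared groups alone gave 0 genes (2244 and 2324 at an unadjusted p under 0.05).

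Among the gene lists, replication-dependent histone genes were higher with prolactin in AML12, with a median change of 0.22 and an adjusted p of 4.69e-09, or adjusted p = 0.819 with an estimated correlation. Of 30 histone genes 5 rose and 0 fell, 11 and 0 adjusted over the list alone, led by H4c14 at 0.91 ± 0.11 (adjusted p = 0.016) and H4c6 at 0.90 ± 0.11 (adjusted p = 0.016). Cholesterol and lipid synthesis genes were lower, with a median of -0.28 and an adjusted p of 6.06e-08, or adjusted p = 0.797 with an estimated correlation. Of 32 members 5 fell and 0 rose, 19 and 1 adjusted over the list alone, among them Msmo1, a sterol synthesis gene, at -0.60 ± 0.08 (adjusted p = 0.021) and the desaturase gene Scd2 at -0.59 ± 0.10 (adjusted p = 0.043). The STAT5 and cytokine receptor list had 3 members higher and 3 lower of 30, 3 and 5 adjusted over the list alone, and did not pass as a whole (adjusted p = 0.981). The list of immediate-early and short-lived transcripts had 3 of 52 members higher and 5 lower, 17 and 10 adjusted over the list alone, at an adjusted p of 0.0507. In it Ier3 rose by 0.95 ± 0.15 (adjusted p = 0.036) and Ccn1 by 0.80 ± 0.14 (adjusted p = 0.043). MYC targets, oxidative phosphorylation genes and hepatocyte genes had the same adjusted p of 0.0507, with medians of -0.06, -0.05 and 0.07. In these lists the ribosome biogenesis gene Rrs1 changed by -0.45 ± 0.08 (adjusted p = 0.050), no oxidative phosphorylation gene passed, and Tat, which encodes tyrosine aminotransferase, rose by 0.90 ± 0.11 (adjusted p = 0.017). In the list of unfolded protein and heat shock genes (adjusted p = 0.0699) Herpud1 changed by -0.83 ± 0.09 (adjusted p = 0.015) and Chac1 by -0.63 ± 0.10 (adjusted p = 0.036). Among core clock genes (adjusted p = 0.981) Nr1d2 rose by 0.68 ± 0.08 (adjusted p = 0.016) while Per1 fell. The p53 list held Ddit4 at -0.72 ± 0.10 (adjusted p = 0.025), and the cell cycle list Kif11 at 0.43 ± 0.07 (adjusted p = 0.032). The adjusted p of the lists not given a value here lay between 0.287 for leukocyte markers and 0.981 for cell cycle genes.

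**Figure D1:**
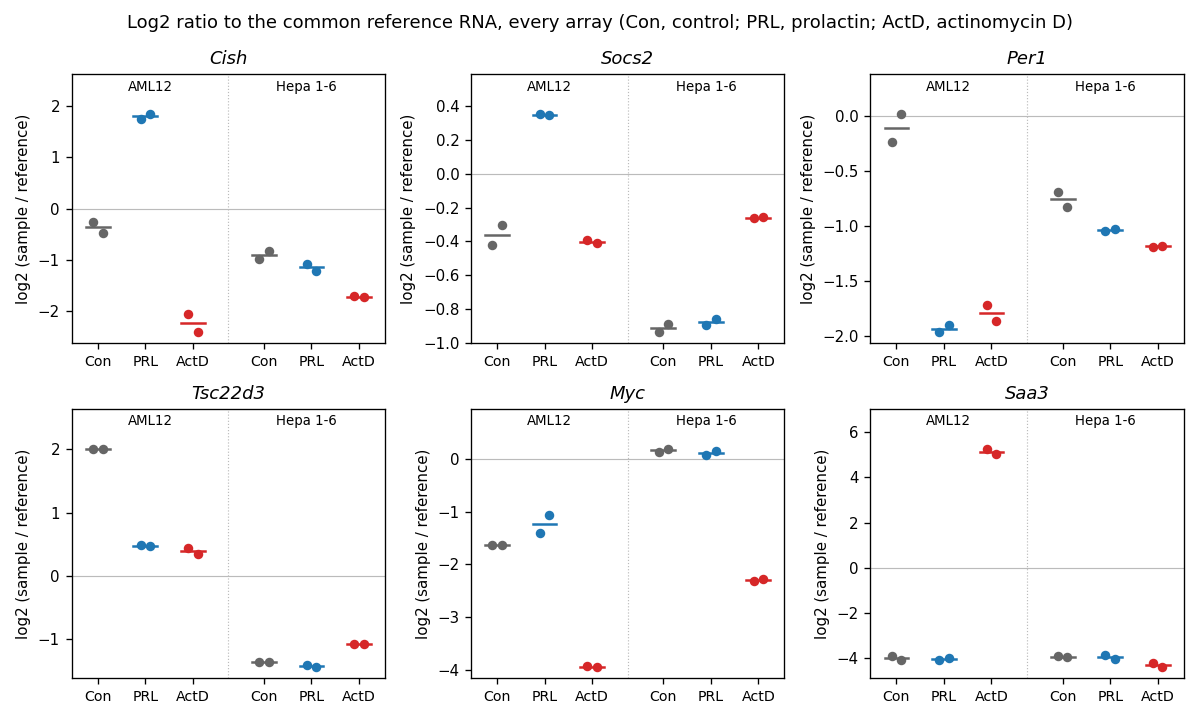
Log2 ratio of sample over reference RNA (vertical axis) for Cish, Socs2, Per1, Tsc22d3, Myc and Saa3 on each of the 12 arrays; dots are arrays, bars are group means, and the groups are serum-free control (Con), prolactin (PRL) and actinomycin D (ActD) in AML12 and Hepa 1-6. Cish lies at 1.76 and 1.85 on the AML12 prolactin arrays, against -0.26 and -0.48 on the AML12 controls.

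The second comparison asked which genes prolactin changed in Hepa 1-6. Slc30a1, which encodes a zinc exporter, rose by 0.86 ± 0.06 (adjusted p = 0.015), and the linker histone gene H1f2 rose by 1.19 ± 0.11 (adjusted p = 0.031). Nipal1, a putative magnesium transporter gene, rose by 0.93 ± 0.10 (adjusted p = 0.043), Bpgm, which encodes a mutase of red-cell glycolysis, by 0.67 ± 0.06 (adjusted p = 0.031), and Nab2, a corepressor of EGR proteins, by 0.65 ± 0.07 (adjusted p = 0.045). The cardiac actin gene Actc1 changed by -0.70 ± 0.07 (adjusted p = 0.043). These were the 6 genes that passed of 16549, 5 higher and 1 lower, while 1359 had an unadjusted p under 0.05. Falls with the next largest moderated t did not pass, which were Dusp1 at -0.72 ± 0.09 (adjusted p = 0.060), Lyst at -0.41 ± 0.05 (adjusted p = 0.087), Pgam2 at -0.58 ± 0.08 (adjusted p = 0.099) and Dusp14 at -0.44 ± 0.06 (adjusted p = 0.12). Cholesterol and lipid synthesis genes had a median of 0.06 and an adjusted p of 0.00121, or adjusted p = 0.948 with an estimated correlation. Of its members 0 of 32 passed in limma, 1 adjusted over the list alone, with Idi1 nearest at 0.30 ± 0.05 (adjusted p = 0.17). No other list passed. The nearest were immediate-early and short-lived transcripts and NRF2 and xenobiotic response genes (adjusted p = 0.0754 for both), and the MYC, STAT5 and interferon lists had adjusted p of 0.583, 0.583 and 0.583. The split of calls was 5 higher and 2 lower after median centring and 4 higher and 2 lower after quantile normalization. Limma gave 0 genes with the highest feature per gene (1280 at an unadjusted p under 0.05), or with fits on the 6 Hepa 1-6 arrays (1376) or the compared groups alone (1524). With the replicate number as a block it also gave 0 (1424). Each of the 6 genes lost the call without at least 1 array. The count was 1 without either AML12 control or the first Hepa 1-6 prolactin array, 2 without either AML12 prolactin or actinomycin D array, 3 and 13 without the first and second Hepa 1-6 control, and 12 without the second Hepa 1-6 prolactin array.

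The difference between the lines' responses to prolactin was tested directly, as Hepa 1-6 minus AML12. Cish differed by -2.41 ± 0.18 (adjusted p = 0.0070), with responses of 2.17 in AML12 and -0.24 in Hepa 1-6, and Socs2 by -0.68 ± 0.08 (adjusted p = 0.039). Edn1 differed by -2.02 ± 0.18 (adjusted p = 0.0083) and Pde4b by -1.83 ± 0.12 (adjusted p = 0.0042), each having risen in AML12. Genes that fell in AML12 differed the other way, Per1 by 1.54 ± 0.14 (adjusted p = 0.0083), Tsc22d3 by 1.46 ± 0.08 (adjusted p = 0.0012), Klf15 by 1.39 ± 0.13 (adjusted p = 0.011) and Klf9 by 1.00 ± 0.08 (adjusted p = 0.0083), and Bcl6 by 0.85 ± 0.09 (adjusted p = 0.016). In all, 20 genes differed, 9 with a higher response in Hepa 1-6 and 11 with a lower one. The split was 11 and 25 after median centring and 11 and 18 after quantile normalization. Ch25h, Dusp10 and Id3 also responded lower in Hepa 1-6, and Pex11a and Herpud1 higher. Cholesterol and lipid synthesis genes differed with a median of 0.39 and an adjusted p of 1.5e-10, or adjusted p = 0.43 with an estimated correlation. In this list 0 of 32 members differed, 16 adjusted over the list alone. Histone genes differed with a median of -0.19 (adjusted p = 3.61e-05; adjusted p = 0.969 with an estimated correlation), a call lost without the first AML12 prolactin array. Immediate-early and short-lived transcripts had a median of -0.13 and MYC targets 0.0763 (adjusted p = 0.0127 and 0.0176), both with adjusted p = 0.969 with an estimated correlation. Both lists lost the call without the second AML12 prolactin array, the second Hepa 1-6 control or the second Hepa 1-6 prolactin array. MYC targets also lost it without the second AML12 control and with the highest feature per gene. Cish and Tsc22d3 kept the call whichever array was left out. The count of 20 became 3 without the first Hepa 1-6 prolactin array, 10 without the second AML12 control and 12 without either Hepa 1-6 actinomycin D array.

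Averaged over both lines, Per1 and Tsc22d3 fell with prolactin, at -1.05 ± 0.07 (adjusted p = 0.0019) and -0.79 ± 0.04 (adjusted p = 0.00060), and prolactin raised Nipal1 by 0.89 ± 0.07 (adjusted p = 0.0037) and H1f2 by 0.88 ± 0.08 (adjusted p = 0.0057). Cish rose by 0.97 ± 0.09 (adjusted p = 0.0082) on average, and the apoptosis inhibitor gene Bcl2l1 changed by -0.53 ± 0.07 (adjusted p = 0.030). The averages of Per1, Tsc22d3 and Cish came mostly from AML12 and do not show a shared response. In Hepa 1-6 these genes changed by -0.28, -0.06 and -0.24, none past the threshold, and their responses differed between the lines. Cxcl10, Npy5r and Cyp2c29 were also among the largest average rises, and Lrriq3, Ccn2 and Tfec among the largest falls. Per1, Tsc22d3, Nipal1 and H1f2 kept the call whichever array was left out. In this test 82 genes passed, 45 higher and 37 lower. Histone genes were higher (median 0.16, adjusted p = 1.14e-06; adjusted p = 0.861 with an estimated correlation), with 1 of 30 members past the threshold and 12 adjusted over the list alone. Cholesterol and lipid synthesis genes were lower on average (median -0.07, adjusted p = 0.0358; adjusted p = 0.993 with an estimated correlation), with 0 members past in limma and 0 adjusted over the list alone, although the lines differed in direction. That call was lost without the second AML12 control, the second AML12 prolactin array, the second Hepa 1-6 control or either Hepa 1-6 prolactin array. The count of 82 was 42 and 17 without the AML12 controls, 53 without the first AML12 prolactin array, 27 and 42 without the Hepa 1-6 controls, 15 and 19 without the Hepa 1-6 prolactin arrays and 44 without either Hepa 1-6 actinomycin D array. Across genes, which are not independent replicates, the lines' responses to prolactin correlated at r = 0.116 (Spearman 0.123), and 54.3% of genes had the same sign. The lists of genes called in each line shared 3 higher genes, against 0.036 for independent lists, and 0 lower genes. Both lists use the same estimate of the spread per gene, so they are not independent even without a shared response.

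Myc, which encodes a growth-promoting transcription factor, was fixed as a gene of interest in every comparison. Its log2 ratios to the reference were -1.63 on both AML12 controls, -1.39 and -1.05 with prolactin, and -3.93 and -3.95 with actinomycin D. In Hepa 1-6 they were 0.14 and 0.19 in controls, 0.08 and 0.15 with prolactin, and -2.31 and -2.28 with actinomycin D. The change with prolactin was 0.41 ± 0.10 (adjusted p = 0.10) in AML12 and -0.06 ± 0.10 (adjusted p = 0.94) in Hepa 1-6, neither past the threshold, and its difference between lines did not pass either, at -0.46 ± 0.14 (adjusted p = 0.31). Myc fell with actinomycin D in both lines, with changes of -2.31 ± 0.10 (adjusted p = 1.3e-06) and -2.46 ± 0.10 (adjusted p = 2.6e-06). Hepa 1-6 controls had more Myc than AML12 controls, by 1.80 ± 0.10 (adjusted p = 1.2e-06).

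The next comparison asked which transcripts fell or rose when transcription was blocked in AML12. Ccn2, a short-lived transcript of a matricellular growth factor, changed by -5.76 ± 0.14 (adjusted p = 1.4e-07), and the kinase gene Plk2 by -4.35 ± 0.13 (adjusted p = 2.6e-07). Zinc finger genes made up 4 of the 10 largest falls, which were Zfp39 at -4.85 ± 0.28, Zfp799 at -4.76 ± 0.17, Zfp472 at -4.62 ± 0.11 and Zfp282 at -4.32 ± 0.12. Saa3, which encodes serum amyloid A3, rose by 9.12 ± 0.11 (adjusted p = 6.8e-09), and Saa1 by 6.81 ± 0.07 (adjusted p = 3.6e-09). Lcn2, which encodes an iron-sequestering protein, rose by 6.08 ± 0.12 (adjusted p = 8.4e-08), Ptgs2, which encodes cyclooxygenase 2, by 6.20 ± 0.17 (adjusted p = 2.0e-07), and the chemokine gene Cxcl5 by 6.77 ± 0.13 (adjusted p = 9.0e-08). Saa2, Mgarp, Gbp3, Nos2 and Wfdc18 rose by 5.02 to 6.08, and Rasl11b, Fam222a, Wdr5b and Rnf43 changed by -4.10 to -4.39. The size of the Gbp3 rise is uncertain, since its mean log2 ratio in AML12 controls was -7.49. Of 16549 genes, 8863 passed the threshold, 4640 higher and 4223 lower, and 2013 of them changed at least 2-fold, 775 higher and 1238 lower. Median centring moved the median of all genes by 0.108 and gave 5848 higher and 3417 lower genes.

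The zinc finger list was lower in AML12 with actinomycin D, with a median of -1.26 and an adjusted p of 3.05e-17, which held with an estimated correlation (adjusted p = 0.0169). Of its 51 members 48 fell, with Zfp189 at -4.03 ± 0.15, and 1 rose, Klf12, at 0.49 ± 0.15 (adjusted p = 0.026), a call lost under 7 of 22 alternatives. The counts were the same adjusted over the list alone. Another 5 lists passed at the preset correlation and not with an estimated one (adjusted p = 0.386 for each). Immediate-early and short-lived transcripts had a median of -1.23 (adjusted p = 2.42e-09), with 38 of 52 lower and 6 higher, also adjusted over the list alone, and Dusp1 at -3.85 ± 0.09, although Spry4 rose by 3.56 ± 0.29. Cell cycle genes had a median of -0.81 (adjusted p = 2.53e-13), with 47 of 52 lower, 47 adjusted over the list alone, among them the mitotic kinase gene Plk1 at -2.12 ± 0.09. Histone genes had a median of -0.86 (adjusted p = 5.36e-08), with 24 of 30 lower, 24 adjusted over the list alone, and H2ac15 at -2.84 ± 0.16. MYC targets had a median of -0.42 (adjusted p = 2.43e-05), with 23 of 32 lower, 24 adjusted over the list alone, including the ribosome biogenesis genes Ppan at -2.28 ± 0.08 and Nop56 at -1.86 ± 0.08. Glycolysis genes went the other way, with a median of 0.98 (adjusted p = 1.33e-05) and 16 of 19 higher, 16 adjusted over the list alone. In this list Pdk1, which restrains pyruvate oxidation, rose by 2.44 ± 0.12 and the hexokinase gene Hk2 by 2.24 ± 0.12, while Gapdh, measured with 1 feature, changed by -3.04 ± 0.20. Innate immune and NF-kB genes had a median of 0.29 (adjusted p = 0.043; adjusted p = 0.522 with an estimated correlation), with 23 of 43 higher and 10 lower, 24 and 10 adjusted over the list alone. The inhibitors Nfkbia at -2.64 ± 0.14 and Tnfaip3 at -1.89 ± 0.12 were among the lower ones. That call was lost after median centring, after quantile normalization, with the highest feature per gene, and without any 1 of the Hepa 1-6 control or actinomycin D arrays.

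The remaining lists did not pass as a whole in AML12 with actinomycin D, although members changed. Interferon-stimulated genes had 13 of 26 higher and 5 lower (adjusted p = 0.0756), with Gbp2 at 2.06 ± 0.10. Hepatocyte genes had 21 of 55 higher and 10 lower (adjusted p = 0.177), and the transcription factor gene Foxa2 in this list changed by -3.31 ± 0.10. The p53 targets had 9 higher and 15 lower of 28 (adjusted p = 0.208), with the death receptor gene Fas at 2.06 ± 0.09. STAT5 and cytokine receptor genes had 8 higher and 14 lower of 30 (adjusted p = 0.221). Ribosomal protein genes had 17 higher and 19 lower of 70 (adjusted p = 0.508) and oxidative phosphorylation genes 14 and 18 of 65 (adjusted p = 0.548), both with a median of -0.03. The cholesterol list had 9 higher and 9 lower of 32 (adjusted p = 0.901), the unfolded protein and heat shock list 11 and 10 of 31 (adjusted p = 0.847), and the NRF2 and xenobiotic list 13 and 9 of 36 (adjusted p = 0.847). Matrix and TGF-beta targets, fibroblast markers, endothelial markers and leukocyte markers had adjusted p of 0.506, 0.508, 0.223 and 0.208, and biliary markers and core clock genes 0.269 and 0.409. In these lists the leukocyte gene Aif1 rose by 2.41 ± 0.16, the biliary gene Sox9 changed by -2.36 ± 0.10 and the clock gene Rora rose by 1.35 ± 0.11. Where a list's median, mean and test differed in sign, in this or another comparison, the list did not pass there.

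In Hepa 1-6, actinomycin D lowered Trib1, which encodes a pseudokinase, and Rnf43, an inhibitor of Wnt signalling, with changes of -4.76 ± 0.08 (adjusted p = 2.2e-07) and -4.21 ± 0.22 (adjusted p = 6.2e-06). The largest rises included immune genes, which were the mannose receptor gene Mrc1 at 4.82 ± 0.35 (adjusted p = 2.3e-05) and the chemokine genes Cxcl2 at 4.09 ± 0.26 (adjusted p = 1.3e-05), Ccl5 at 4.05 ± 0.08 (adjusted p = 2.4e-07) and Cxcl1 at 3.97 ± 0.17 (adjusted p = 2.8e-06). The innate immune and NF-kB list did not pass as a whole in this comparison. The growth factor gene Csf2 rose by 3.84 ± 0.30 (adjusted p = 3.2e-05), and the glucose transporter gene Slc2a4 by 3.84 ± 0.24 (adjusted p = 1.3e-05). Trpv3, Sprr2h, Selenbp1 and Tfr2 rose by 3.78 to 4.36. The other large falls were Rasgef1b, Gapdh, Snhg8, Wdr5b, Dynlt1a, Mkrn3, Lcmt2 and Zfp282, from -4.27 to -3.57. In all, 8417 genes passed, 4615 higher and 3802 lower, of which 1655 changed at least 2-fold, 895 higher and 760 lower.

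In Hepa 1-6, 7 lists passed with actinomycin D at the preset correlation, and 0 with an estimated one, where 2 had an unadjusted p under 0.05. Zinc finger genes had a median of -0.56 (adjusted p = 8.89e-08; adjusted p = 0.14 with an estimated correlation), with 32 of 51 lower and 4 higher, 33 and 4 adjusted over the list alone. Zfp87 changed by -2.91 ± 0.06, while Zfp239 rose by 1.28 ± 0.21. Histone genes (median -0.98, adjusted p = 8.89e-08), cholesterol and lipid synthesis genes (-0.55, adjusted p = 1.83e-07), MYC targets (-0.46, adjusted p = 4.81e-07) and immediate-early and short-lived transcripts (-0.52, adjusted p = 7.78e-06) were lower, and interferon-stimulated genes higher (0.46, adjusted p = 0.00371), each with adjusted p = 0.349 with an estimated correlation. Cell cycle genes were lower (median -0.28, adjusted p = 0.00371; adjusted p = 0.724 with an estimated correlation). The counts of lower members were 21 of 30 histone genes, 22 of 32 cholesterol genes, 21 of 32 MYC targets, 31 of 52 immediate-early transcripts and 23 of 52 cell cycle genes, the same adjusted over each list alone. Of 26 interferon-stimulated genes 15 rose and 1 fell, 16 and 2 adjusted over the list alone, with Ifit1 at 2.84 ± 0.44. The sterol synthesis genes Msmo1 and Fdps changed by -1.77 ± 0.08 and -1.53 ± 0.06, and Insig2, which restrains that pathway, rose by 1.43 ± 0.07. H1f5 changed by -3.03 ± 0.14, the BMP target Id1 by -3.21 ± 0.12 and the Wnt target Axin2 by -2.86 ± 0.20, while Egr2 and Atf3 rose by 2.38 ± 0.11 and 1.96 ± 0.12. Glycolysis genes had 11 of 19 higher and 4 lower and did not pass (adjusted p = 0.302), nor did innate immune genes (adjusted p = 0.319) or p53 targets (adjusted p = 0.383). Ddit3, a stress-response gene, rose by 2.44 ± 0.07 in a list that did not pass (adjusted p = 0.946).

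**Figure D2:**
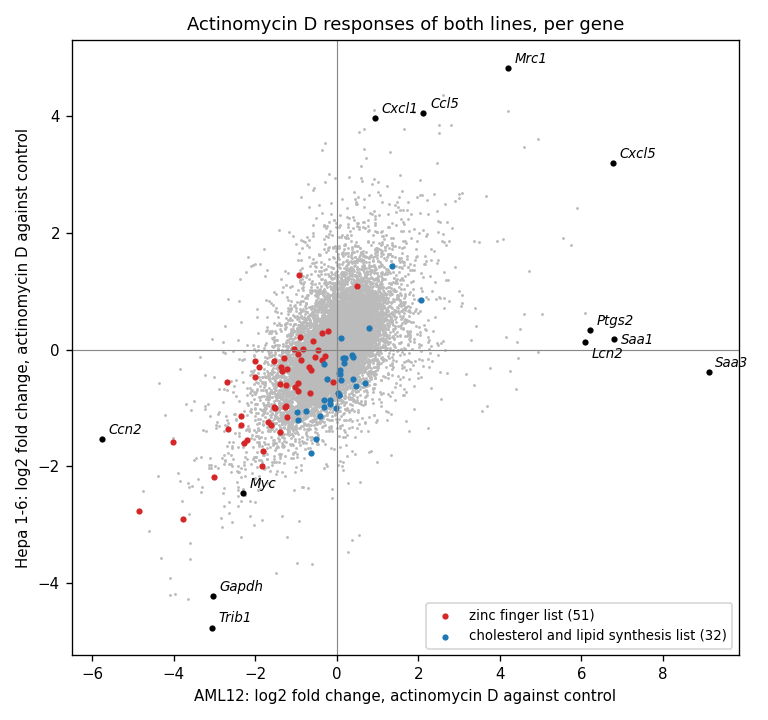
Log2 change with actinomycin D in AML12 (horizontal axis) and Hepa 1-6 (vertical axis) for each of 16549 genes; red points are the 51 zinc finger genes, blue points the 32 cholesterol and lipid synthesis genes, and black points labelled genes. Saa3 lies at 9.12 in AML12 and -0.38 in Hepa 1-6, whereas Myc lies near -2.31 and -2.46.

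The difference between the lines' responses to actinomycin D was tested as Hepa 1-6 minus AML12. The Saa genes, Lcn2 and Ptgs2 responded lower in Hepa 1-6, with differences of -9.50 ± 0.16 (adjusted p = 7.4e-08) for Saa3, -6.63 ± 0.10 (adjusted p = 6.7e-08) for Saa1, -5.45 ± 0.26 (adjusted p = 1.9e-05) for Saa2, -5.94 ± 0.16 (adjusted p = 2.0e-06) for Lcn2 and -5.87 ± 0.24 (adjusted p = 1.6e-05) for Ptgs2. Cxcl1 responded higher, by 3.02 ± 0.24 (adjusted p = 0.00012), and the innate immune and NF-kB list did not pass (adjusted p = 0.218). Ccn2 and Plk2 responded higher, by 4.23 ± 0.20 (adjusted p = 1.8e-05) and 3.77 ± 0.18 (adjusted p = 2.0e-05), having fallen in AML12. Bend5, Hsd3b4 and Cyp3a44 also responded higher, and Cyp3a44 lost the call under 11 of 21 alternatives. In all, 4972 genes differed, 2853 higher and 2119 lower, or 2303 and 2647 after median centring. Of these, 1492 passed in both lines in the same direction, 632 in opposite directions, 2789 in 1 line and 59 in neither. Zinc finger genes fell less in Hepa 1-6, with a median difference of 0.64 (adjusted p = 1.1e-10; adjusted p = 0.0633 with an estimated correlation) and 32 of 51 members higher, 38 adjusted over the list alone. Zfp189 differed by 2.45 ± 0.21. Cell cycle genes differed in the same direction (median 0.63, adjusted p = 3.5e-09; adjusted p = 0.489 with an estimated correlation), with 29 of 52 higher, 32 adjusted over the list alone, and Aurka at 1.45 ± 0.12. Cholesterol and lipid synthesis genes responded lower (median -0.54, adjusted p = 9.3e-11; adjusted p = 0.206 with an estimated correlation), with 22 of 32 lower, 25 adjusted over the list alone, and Scd1 at -1.26 ± 0.11. Glycolysis genes also responded lower (median -0.82, adjusted p = 8.29e-07; adjusted p = 0.489 with an estimated correlation), with 13 of 19 lower, also adjusted over the list alone, and the lactate exporter gene Slc16a3 at -2.13 ± 0.12. Immediate-early transcripts and p53 targets both had a median difference of 0.38 (adjusted p = 0.00157 and 0.00529; adjusted p = 0.513 and 0.347 with an estimated correlation), and Dusp1 differed by 3.52 ± 0.12. Matrix and TGF-beta targets (-0.22, adjusted p = 0.0236), biliary markers (0.18, adjusted p = 0.0434) and leukocyte markers (-0.20, adjusted p = 0.0409) passed with less margin, with adjusted p = 0.551, 0.489 and 0.303 with an estimated correlation. The immediate-early and biliary calls were lost with the highest feature per gene, and the matrix and leukocyte calls after quantile normalization. The matrix, biliary and leukocyte lists lost the call without the first Hepa 1-6 control, and biliary and leukocyte markers also without either Hepa 1-6 prolactin array or the first Hepa 1-6 actinomycin D array. Biliary markers also lost it without the second AML12 actinomycin D array or the second Hepa 1-6 control, and leukocyte markers without the first AML12 actinomycin D array.

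Averaged over both lines, actinomycin D raised the cytokine genes Cxcl5 by 4.98 ± 0.09 (adjusted p = 3.1e-08) and Csf3 by 4.27 ± 0.17 (adjusted p = 4.7e-07), and Mrc1 by 4.51 ± 0.25 (adjusted p = 2.2e-06). It lowered Rnf43, Zfp282 and Trib1, with changes of -4.16 ± 0.16 (adjusted p = 4.2e-07), -3.95 ± 0.08 (adjusted p = 4.4e-08) and -3.91 ± 0.06 (adjusted p = 2.0e-08). Mgarp and Cxcl2 were also among the 5 largest average rises, and Wdr5b and Rasgef1b among the 5 largest falls. In this test 10160 genes passed, 5629 higher and 4531 lower, or 6553 and 3881 after median centring. Zinc finger genes were lower (median -0.86, adjusted p = 2.69e-14), which held with an estimated correlation (adjusted p = 0.0279), with 44 of 51 members lower. The other lists that passed at the preset correlation were lower for cell cycle genes (-0.55, adjusted p = 1.26e-09), immediate-early transcripts (-0.84, adjusted p = 4.58e-09), histone genes (-1.01, adjusted p = 1.33e-08), MYC targets (-0.44, adjusted p = 3.77e-07) and cholesterol genes (-0.25, adjusted p = 0.00309). They were higher for glycolysis genes (0.75, adjusted p = 0.00244), interferon-stimulated genes (0.59, adjusted p = 0.0232) and innate immune genes (0.32, adjusted p = 0.0396). With an estimated correlation the adjusted p was 0.44 for the MYC, interferon, immediate-early, cell cycle, histone and cholesterol lists and 0.582 for glycolysis and innate immune genes. Innate immune and interferon-stimulated genes lost the call with the highest feature per gene, and innate immune genes also under both scalings and without the second Hepa 1-6 actinomycin D array. Across genes the lines' responses to actinomycin D correlated at r = 0.559 (Spearman 0.544), and 71.2% of genes had the same sign. The lines shared 2683 genes called higher, against 1294 for independent lists, and 2509 called lower, against 970, while 284 and 348 were called in opposite directions. These lists too use the same estimate of the spread per gene and are not independent.

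The responses to the 2 treatments were compared within each line, where they share the control arrays. Across genes, prolactin and actinomycin D responses correlated at r = 0.133 in AML12 and 0.158 in Hepa 1-6. Simulated groups with no effect that share their controls correlated at 0.499. That value is not comparable, since the real actinomycin D changes spread more widely, which lowers a correlation. Their standard deviations were 0.748 in AML12 and 0.661 in Hepa 1-6, against 0.272 and 0.225 for prolactin. The real responses correlated at 0.231 in AML12 without the first control. In Hepa 1-6 they correlated at 0.298 without the second control and 0.105 without the second prolactin array. The covariances were 0.0271 and 0.0235, against a simulated 0.0192, so they exceeded it by 0.00789 and 0.00429. With each treatment set against its own control array, the correlations were 0.0499 and 0.0300 in AML12 and 0.0532 and -0.0185 in Hepa 1-6. In AML12, 48 genes fell with both treatments, against 23.2 for independent lists, and 42 rose with both, against 33.4; Per1 was among the genes that fell with both. Another 52 genes rose with prolactin and fell with actinomycin D, and 14 did the reverse. Genes raised by prolactin thus fell with actinomycin D more often than they rose. No value for independent lists was computed for opposite directions. In Hepa 1-6, 2 genes rose with both, against 1.39, and 1 fell with both, against 0.230. With 2 controls per line the split left 1 array each, so part of the excess may come from the shared controls. The lists of calls also use the same estimate of the spread per gene.

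The serum-free controls of the lines were compared to give the baseline on which the treatments acted. Nkd1, a Wnt pathway antagonist, was higher in Hepa 1-6 by 9.50 ± 0.27 (adjusted p = 3.1e-08), and the Wnt target Axin2 by 7.17 ± 0.20. Afp, the fetal liver protein gene, was higher by 5.82 ± 0.08 (adjusted p = 2.2e-09), whereas Hp, which encodes haptoglobin, was lower at -6.33 ± 0.12 (adjusted p = 5.0e-09), and Apoh at -7.16 ± 0.33 (adjusted p = 4.1e-07). The cholangiocyte keratin gene Krt19 was lower at -8.22 ± 0.10 (adjusted p = 8.2e-10), and Gsta3, a glutathione transferase gene, at -8.20 ± 0.08 (adjusted p = 4.4e-10). Kctd12, Ppp1r3c, Dppa4 and Pdcd1lg2 were also among the 5 genes highest in Hepa 1-6, and Zfp239, Tex13b, Slco3a1, Tpd52l1 and Sult1a1 were the 5 lowest. Of 16549 genes 10237 differed, 5312 higher and 4925 lower in Hepa 1-6, and 4122 of them at least 2-fold. MYC targets were higher in Hepa 1-6 (median 0.91, adjusted p = 3.66e-06; adjusted p = 0.454 with an estimated correlation), with 27 of 32 higher, 28 adjusted over the list alone. Glycolysis genes (0.66, adjusted p = 0.00109) and cell cycle genes (0.52, adjusted p = 0.00128) were also higher, with adjusted p = 0.622 and 0.645 with an estimated correlation. Lower lists were NRF2 and xenobiotic genes (-0.94, adjusted p = 0.00109; adjusted p = 0.109 with an estimated correlation), histone genes (-0.84, adjusted p = 0.00109) and oxidative phosphorylation genes (-0.24, adjusted p = 0.00379), the last 2 with adjusted p = 0.622 with an estimated correlation. Biliary markers (-1.84, adjusted p = 0.0044) and zinc finger genes (-0.57, adjusted p = 0.00686) were lower with adjusted p = 0.454, and hepatocyte genes (-0.24, adjusted p = 0.0406) with adjusted p = 0.645, with an estimated correlation. The hepatocyte call was lost after quantile normalization and without the first AML12 control.

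**Figure D3:**
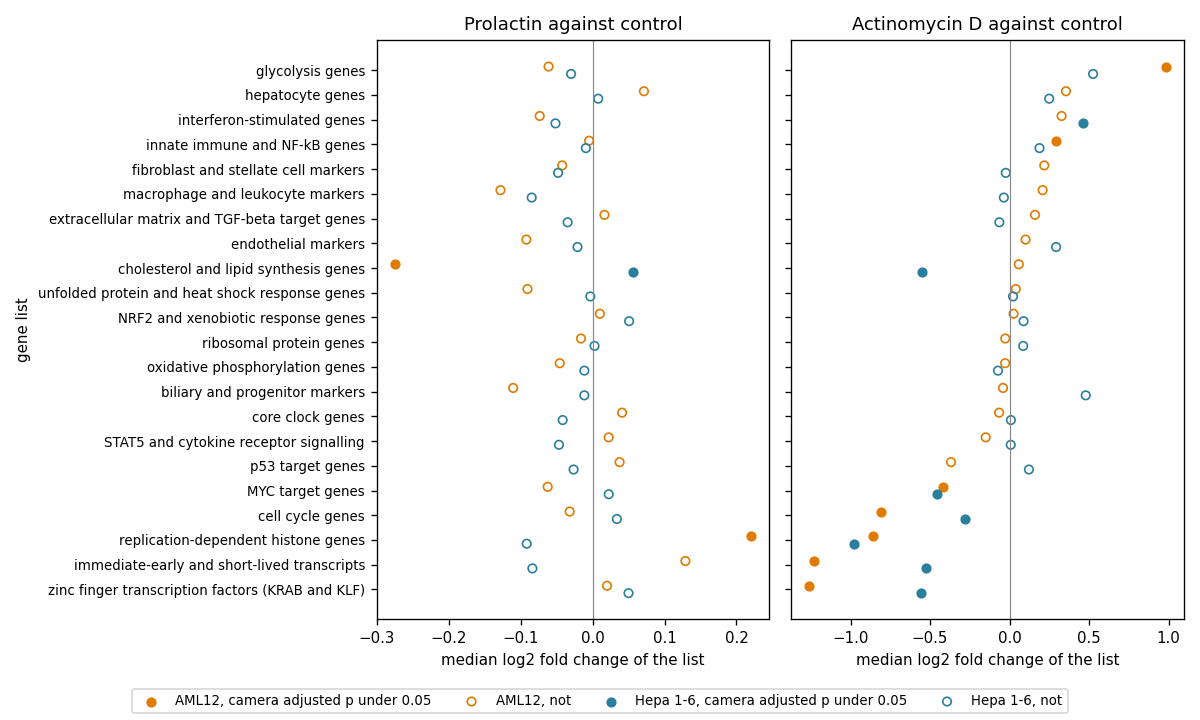
Median log2 change of each of the 22 gene lists with prolactin and, in a panel with a wider horizontal range, with actinomycin D, for AML12 and Hepa 1-6; filled points had a camera adjusted p under 0.05 at the preset correlation. Zinc finger genes have the lowest actinomycin D median in AML12, at -1.26, and lie at -0.56 in Hepa 1-6.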

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

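Tests of total RNA, of leukocytes, of the other glucocorticoid-responsive genes and of the control arrays were chosen only after the result was seen. The tests of gene span and both tests of the zinc finger genes were set out before. Results are given here because the lines' responses to the same treatment differed in an interaction test, or because a signal lay in features the comparisons left out. All differences are Hepa 1-6 minus AML12 on the log2 scale with limma's adjusted p. No group had enough arrays to test whether a single array stood apart.

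The response to prolactin differed between the lines for 20 genes. Among the genes named for prolactin within a line, Cish differed by -2.41 (adjusted p = 0.0070), Edn1 by -2.02, Pde4b by -1.83, Ch25h by -1.42 and Chst15 by -1.33, with adjusted p up to 0.044. Per1 differed by 1.54, Tsc22d3 by 1.46, Klf15 by 1.39, Bpgm by 1.00 and Klf9 by 0.999, with adjusted p from 0.0012 to 0.011.

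The response to actinomycin D differed for 4972 genes. Among those named within a line, Saa3 differed by -9.50 (adjusted p = 7.4e-08), Saa1 by -6.63, Lcn2 by -5.94, Ptgs2 by -5.87, Saa2 by -5.45, Wfdc18 by -4.42, Gbp3 by -3.96, Nos2 by -3.64, Cxcl5 by -3.58 and Mgarp by -3.46, each having risen more in AML12. Gbp3 had a mean log2 ratio of -7.49 in AML12 controls, against -1.69 in Hepa 1-6 controls. Ratios that low can lie at the detection floor, so the size of its difference is uncertain. Mkrn3 differed by -2.67, Dynlt1a by -2.33, Trib1 by -1.70, Snhg8 by -1.38, Gapdh by -1.17 and Rasgef1b by -0.61, each having fallen more in Hepa 1-6. Ccn2 differed by 4.23, Plk2 by 3.77, Fam222a by 3.09, Zfp799 by 2.34, Rasl11b by 2.23, Zfp39 by 2.09, Zfp472 by 1.51 and Zfp282 by 0.746, each having fallen more in AML12. Sprr2h differed by 3.20, Tfr2 by 3.12, Cxcl1 by 3.02, Selenbp1 by 2.17, Ccl5 by 1.93 and Csf2 by 1.34 (adjusted p = 0.046), each having risen more in Hepa 1-6.

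Gene lists differed between the lines in camera at its preset correlation. For prolactin the median differences were 0.0763 for MYC targets, -0.131 for immediate-early and short-lived transcripts, -0.188 for histone genes and 0.388 for cholesterol and lipid synthesis genes. For actinomycin D they were 0.38 for p53 targets, 0.38 for immediate-early and short-lived transcripts, -0.819 for glycolysis genes, 0.626 for cell cycle genes, -0.542 for cholesterol and lipid synthesis genes, -0.218 for matrix and TGF-beta targets, 0.183 for biliary markers, -0.203 for leukocyte markers and 0.645 for zinc finger genes. With an estimated correlation none passed (camera, 0 of 22 lists for either treatment, 1 and 3 at an unadjusted p under 0.05), and fry found 1 and 16.

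Features without a ratio on all arrays were outside the comparisons. With actinomycin D, 846 features in AML12 and 381 in Hepa 1-6 had a ratio in both controls and on no treated array, against 157 and 136 with prolactin. The reverse, a ratio on both treated arrays and in no control, held for 92 and 169 features with actinomycin D and 217 and 191 with prolactin. Named after the values were seen, as the highest with a known gene for actinomycin D, Smlr1 had a mean control log2 ratio of 3.87 in AML12 and Melk 2.99 in Hepa 1-6. Steap4 had a treated mean of 4.24 in AML12 and Klrc1 3.71 in Hepa 1-6. These ratios were not tested.

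The 139 genes that actinomycin D raised at least 4-fold in AML12 included Saa3 and Lcn2, although the drug blocks transcription. Their median of 2.50 is high by the 4-fold bound that chose them. A loss of total RNA would lift stable transcripts by a like amount, yet an upper percentile of ribosomal protein and oxidative phosphorylation genes was 0.545 and the highest of them 0.779. RNA from leukocytes would raise their markers alike, but the 14 markers had a median of 0.208 and an upper quartile of 0.543, with Lyz1 at 0.20 and Tyrobp at -0.10, while Aif1 (2.41) and Cd14 (1.34) rose. Short genes, which a transcription block may spare, stayed open: the raised genes' median span was 0.54 of that of other genes (10.8 against 20.0 kb, permutation p = 6e-05), short of the bound of 0.5 set before, and genes lowered at least 4-fold were short too (12.5 kb). Fewer competing transcripts would also lift stable ones. The same values argue against that as the source of the 139 rises, as far as the ribosomal protein and oxidative phosphorylation transcripts are stable. Whether the raised transcripts were made during treatment was not measured, and the difference between the lines remains a biological explanation that was not tested.

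Under prolactin in AML12, Per1, Tsc22d3, Klf15, Klf9 and Fkbp5 (-0.80 ± 0.07 (adjusted p = 0.0031), noticed after its values were seen) fell, and all are known to be induced by glucocorticoids. For these 5 genes both controls lay above both prolactin arrays by at least 0.704, against at most 0.251 between replicates. Their mean change was -1.34 against the first control and -1.39 against the second. The rule that named Per1, Tsc22d3, Klf15 and Klf9 asked for such a separation, though not for its size. Fkbp5 was picked by its values, so the separation is no independent test of a single deviating control culture. A high level in both controls stays open. With actinomycin D, which shares these controls, the 5 genes had a median change of -1.53 in AML12, against -1.48 with prolactin, and mean levels within 0.140 of those with prolactin. In Hepa 1-6 their median with actinomycin D was -0.427, so the block of transcription may lower them too, and the labels give no treatment time for the controls. With actinomycin D in AML12, 25 other listed genes had a median of -0.498, 11 lower and 4 higher. Their camera adjusted p was 0.0019, or 0.109 with an estimated correlation. Lower glucocorticoid receptor output may underlie the fall of the 5 genes with prolactin. Yet with prolactin the 25 others had a median of -0.0747 (95% bootstrap interval -0.32 to 0.23, camera adjusted p = 0.713), with Ddit4 (-0.72) and Errfi1 (-0.69) lower and Angptl4 (0.66) higher. Tat, a glucocorticoid-induced gene outside that list, rose by 0.90 ± 0.11 (adjusted p = 0.017). Because these genes went both ways, that explanation stays open too. Only the AML12 maintenance medium held dexamethasone, so the line and its medium cannot be told apart as the source of the difference from Hepa 1-6.

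Zinc finger transcripts fell less with actinomycin D in Hepa 1-6 than in AML12, with a median difference of 0.645 over 51 genes. Scaling between arrays is argued against, since the median was 0.573 after median centring and 0.687 after quantile normalization. A lower starting level in Hepa 1-6 is argued against too, since the 16 members at or above their AML12 level in controls had a median difference of 0.817, and the 35 others 0.643. A slower decay of these transcripts in Hepa 1-6, or a weaker block of transcription, may explain the difference as a hypothesis, and neither was measured. Other lists went both ways, so they do not decide whether the block was weaker in Hepa 1-6. Immediate-early transcripts differed by a median of 0.38 and cell cycle genes by 0.626, but cholesterol and lipid synthesis genes by -0.542. With an estimated correlation the list's adjusted p was 0.0633, so it was not past the threshold there.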

How the results depend on the processing

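Keeping exact zeros as a ratio of 1 was chosen after seeing the data, and the other alternatives before. Counts for actinomycin D and for the baseline stayed within 1.5 times the reported ones under every alternative that counts genes except the minimum fold, and no list past the threshold changed direction. Counts for prolactin moved more. Where no cause is named, the cause was not tested.

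Prolactin in AML12 (210 genes) gave 0 with a fit on the line alone (limma, 2244 at an unadjusted p under 0.05, smallest adjusted p 0.0713) and 0 with the compared groups alone (2324, smallest 0.188). These fits hold fewer arrays. Prolactin in Hepa 1-6 (6 genes) gave 0 in the same fits (1376 and 1524), 0 with the highest feature per gene (1280, smallest adjusted p 0.0501) and 3 with features measured in at least 1 sample of every group. The average over lines (82) gave 24 with the compared groups alone and 53 without the lowest 20% of mean ratios. The difference between lines (20) gave 11 with the compared groups alone, 36 after median centring, 31 without the lowest 20% and 47 with zeros kept. A minimum fold of 2, stricter by construction, left 29, 1, 2013 and 1655 genes for prolactin and actinomycin D in AML12 and Hepa 1-6, 4 and 1486 for the averages, 1351 for the actinomycin D difference and 4122 for the baseline. Tested by themselves, features rather than genes passed in numbers of 780, 19488, 17906, 134, 22027, 47, 10545 and 21244 for prolactin and actinomycin D in AML12, actinomycin D in Hepa 1-6, both averages, both differences and the baseline. For prolactin in AML12, 530 of these features were higher and 250 lower. There 3.93% of features with several symbols or none passed, against 1.75% of features with 1 symbol.

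Same-numbered arrays of a line deviated together weakly, with correlations of 0.0534, 0.159 and 0.0405 in AML12 and 0.0944, 0.0326 and 0.0085 in Hepa 1-6, so they were treated as sharing a number only. With the replicate number as a block, prolactin gave 49 genes in AML12, 0 in Hepa 1-6 (limma, 1424 at an unadjusted p under 0.05), 19 on average and 7 for the difference, and 1 list passed on average. The block also took the threshold from innate immune genes with actinomycin D in AML12 and on average, and from biliary markers in the difference.

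Leaving out 1 array at a time, the lone array left in its group being assumed to vary like the other groups, gave 30 to 183 genes for prolactin in AML12, 1 to 13 in Hepa 1-6, 15 to 97 on average and 3 to 25 for the difference. The ranges were 7154 to 8884, 6508 to 8458, 9241 to 10174 and 3617 to 4955 for actinomycin D in the same order, and 9179 to 10302 for the baseline. Lists past the threshold numbered 2 to 8, 1 to 2, 1 to 4 and 2 to 6 for prolactin, 6 to 8, 7 to 7, 8 to 10 and 6 to 9 for actinomycin D, and 8 to 9 for the baseline. The correlation between lines was 0.526 to 0.561 for actinomycin D and 0.0802 to 0.122 for prolactin, and that between treatments 0.106 to 0.231 in AML12 and 0.105 to 0.298 in Hepa 1-6.

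The number of lists past the threshold depended on the test as well. With an estimated correlation camera left 0 lists for prolactin in AML12, in Hepa 1-6, on average and for the difference (1 each at an unadjusted p under 0.05). It left 1 for actinomycin D in AML12 and on average, 0 in Hepa 1-6 (2) and for the difference (3), and 0 for the baseline (1). With fry they were 1, 0 (1 at an unadjusted p under 0.05), 0 (4) and 1 for prolactin. They were 18, 18, 17 and 16 for actinomycin D in the order AML12, Hepa 1-6, average and difference, and 22 for the baseline. Fry does not compare a list with other genes. Prolactin in AML12 had 5 lists after quantile normalization and 4 with the highest feature per gene. Prolactin in Hepa 1-6 had 3 with the latter. The correlation of the lines' actinomycin D responses (0.559) was 0.605 without the lowest 20% and 0.547 with the highest feature. With 1 control array per treatment, the treatments' responses correlated at 0.0499 and 0.0300 in AML12 and 0.0532 and -0.0185 in Hepa 1-6. That setting removes the shared controls and leaves 1 array per control, and these were not told apart.

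Using the highest feature per gene turned the direction of some list members. These were Uqcrq (0.0415 with prolactin and 0.0914 with actinomycin D in AML12, 0.0399 in Hepa 1-6, 0.0656 on average, -0.0271 in the prolactin difference), Reln (0.0354 with prolactin in Hepa 1-6), Col4a1 (0.607 in AML12 and 0.273 on average with actinomycin D), Vim (0.0116) and Pdgfra (0.0581 in AML12, 0.194 on average). In Hepa 1-6 they were Rpl9 (0.0880), Top2a (0.105), Ngfr (0.284) and Ptprc (-0.0814). Ptprc also turned in the actinomycin D difference (-0.334) and at baseline (0.174), as did Rps15a (0.134), Flt1 (0.810) and Per2 (0.146). Myc turned in the actinomycin D difference after quantile normalization (0.0339), a difference that was not past the threshold. Over all named genes and alternatives, 293 of the prolactin results in AML12 and 79 in Hepa 1-6 fell below the threshold in the same direction, against 33 and 45 for actinomycin D. Cish, Edn1, Per1, Tsc22d3, Klf15, Klf9 and Socs2 lost it in AML12 in the fits with fewer arrays and in no other setting run per gene, and Pde4b also with zeros kept (0.80, adjusted p = 0.061). Signal over background was not used here, so how far low ratios lie at the detection floor is not known.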

Other observations

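The tests of hypoxia-inducible and acute-phase genes were chosen only after the result was seen; the counts over other splits of the arrays were set out before.

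Acute-phase genes are a list added after the rise of the Saa genes was seen. The 19 members left without the Saa genes, Lcn2 and Cd14 had a median log2 change of 0.56 with actinomycin D in AML12, 12 higher and 1 lower. Their camera adjusted p was 0.0012, or 0.069 with an estimated correlation, which did not pass. In Hepa 1-6 the median was 0.26, with 6 higher and 2 lower (camera adjusted p = 0.190). The difference between lines had a median of -0.24, with 6 members lower (camera adjusted p = 0.0031; adjusted p = 0.095 with an estimated correlation). Saa3 had a mean log2 ratio to the reference of -3.99 in AML12 controls, where ratios can lie at the detection floor, so the size of its rise of 9.12 is uncertain. With prolactin 0 of the 19 members passed in limma in AML12, with a median of -0.15 (camera adjusted p = 0.713).

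Glycolysis genes had a median of 0.98 with actinomycin D in AML12, with 16 of 19 higher and 2 lower, Gapdh among them at -3.04, and did not pass with an estimated correlation (adjusted p = 0.386). A candidate explanation is a hypoxia-inducible programme. The test was whether hypoxia-inducible genes outside glycolysis rose too: their median was 1.05 over 26 genes (95% bootstrap interval 0.58 to 1.29), with 21 higher and 2 lower. Without Selenbp1 and Ddit4, which had been named before, 20 of 24 were higher and 1 lower (camera adjusted p = 3.9e-07; adjusted p = 0.109 with an estimated correlation). In Hepa 1-6 the median of the 26 genes was 0.55, with 15 higher and 4 lower. Oxygen was not measured, and longer-lived transcripts than most would rise in the same way on ratios normalized within each array. The test alone therefore does not separate induction from stability. With actinomycin D in AML12, an upper percentile of ribosomal protein and oxidative phosphorylation genes was 0.545 and the highest of them 0.779. The medians of 0.98 and 1.05 lay above both, although the interval's lower end of 0.58 lay above only the first. As far as ribosomal protein and oxidative phosphorylation transcripts are stable, this argues against stability as the source of both medians in AML12. It does not show that hypoxia was the cause.

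Each line's arrays of a treatment and its control were also split in other ways, 18 splits over both lines, which are too few for a share under 0.05. The real split gave 82 genes for prolactin averaged over both lines, and the highest other gave 20, with 1 split, the real one, at 82 or more. For actinomycin D the real split gave 10160 and the highest other 4972, again with 1 split as high. In both cases the highest other was the split that turns 1 line around, which tests the difference between the lines.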
